A study of Mus musculus with 4 samples.

How the data were processed

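Total RNA from mouse cells was hybridised to 4 Affymetrix MG_U74Av2 arrays, 1 sample per array. According to the labels, R1 embryonic stem (ES) cells grown unattached as embryoid bodies for 48 hours with LIF gave 2 arrays, one titled aggregation and the other suspension. R1 cells grown on gelatin under standard conditions gave 1 array, and neurospheres from the telencephalon of embryonic day 13.5 gave 1 array. The labels give both embryoid body arrays the same sample identifier and description, so they were treated as 2 replicates of one group. Nothing says that they came from separate cultures. The p-values therefore measure only the spread between these 2 arrays, which may be technical or may hold a difference between the culture forms their titles name.

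The deposited table holds linear MAS5 signal intensity per probe set, as computed by the authors per the submitters' processing notes. MAS5 combines the perfect-match and mismatch probes of a probe set into a single signal. The version, the scaling target and the settings of MAS5 are not given in the sources used here. Biotin labelling, an antibody-amplified scan and the chip type are recorded per the file headers of the experiment files. The deposited intensity values of the arrays were on different scales. Their trimmed means, with 2% of values left out at each end, were 33.0 for aggregation, 1501 for suspension, 29.9 for neurospheres and 1501 for adherent cells. No detection calls were used, so a low signal was not separated from background.

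Of 12488 probe sets, 66 were AFFX controls and were left out after use as a check of RNA quality. Of the other 12422, the platform annotation paired 10833 with 1 gene, 396 with several genes and 1193 with none. The gene identifiers of 10817 were found in a RefSeq gene table, and 0 symbols had to be updated. Each array was scaled to a trimmed mean of 500, and 32 was added before taking log2. All fold changes are on this log2(value + 32) scale, which understates changes of genes with low signal. Probe sets were kept when they reached the array median on at least 1 of the 4 arrays, which left 8031. For each gene, the probe set with the highest mean log2 value was used. Probe sets with several genes or none stayed as separate entries without a gene name. This gave 6843 features: 6002 named genes, 273 probe sets with several genes and 568 with none.

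One limma model (limma 3.58.1, R 4.3.3) was fitted to the log2 values of all 4 arrays, with neurospheres, embryoid bodies and adherent cells as groups. Variances were moderated by empirical Bayes with an intensity trend. The only residual degree of freedom, 1, came from the 2 embryoid body arrays, and the prior contributed 17.34. The single neurosphere and adherent arrays were assumed to vary like the embryoid body arrays. Neurospheres were compared with the mean of the embryoid body mean and the adherent array, and the embryoid body mean was compared with the adherent array. P-values were two-sided and adjusted by Benjamini-Hochberg over all features, with a threshold of 0.05. As descriptions without a test, features at least 2-fold apart from every array of the other group were counted. The aggregation and suspension arrays were compared by counts and correlation alone.

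The grouping, tests, alternatives, 21 gene lists and rule for named genes were set before the data were examined. The lists covered pluripotency, neural progenitors, neurons, glia, other cell types the cultures could hold, germ layers, pathways, proliferation, metabolism, adhesion and stress. Of 442 list entries, 390 were on the array, and 295 distinct genes were tested, 15 of them in more than 1 list. List members below the array median on all 4 arrays were not tested, so list counts and medians leave them out. Calls were counted after adjustment over all features and adjusted over the list alone. The median difference of each list was placed among 10000 random lists of the same size matched on mean expression in 10 bins, as a description of these arrays. Named genes were the 10 largest called differences each way between neurospheres and R1 cells that were at least 2-fold against each R1 array. For embryoid bodies against adherent cells, the 5 largest each way were taken in the same manner. For aggregation against suspension, the 3 largest differences each way were taken. Up to 4 called members of each list were added by size, or, where none was called, the 2 with the highest mean. A fixed set of marker genes was also taken: Pou5f1, Zfp42, Sox2, Nes, Vim, Fabp7, Pax6, Gfap, Tubb3, Gata4, Gata6, Afp, T, Fgf5, Cdh1 and Cdh2. Of these, Pax6, Gata6, Afp and Fgf5 did not reach the signal filter, and T was not paired with a probe set in the annotation used. Other genes are named in the text with a statement that they were chosen after their values were seen.

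The code was tested on simulated data with the means of the 6843 features and with variances drawn from the fitted prior, and 200 features were changed. For neurospheres against R1 cells it recovered 2% of changes of 1 log2 unit, 60% at 2 units, 74% at 3 units and 100% at 4 units, and 9 of 127 calls (7.09%) were false. For embryoid bodies against adherent cells the recovered shares were 14%, 66%, 80% and 86%, and 15 of 138 calls (10.9%) were false. In the data 1377 features were called for neurospheres and 24 for embryoid bodies. The unadjusted p needed for a call therefore differed from the simulation, and the recovered shares do not carry over. All simulated arrays varied alike, so the false shares do not check that assumption for the single arrays. Alternatives changed the scaling, pseudocount, signal filter, variance model, choice of probe set, control arrays and number of groups, or left out an embryoid body array. An analysis without probe sets whose identifiers end in _r_at was added after seeing the data. Genomic coordinates are not reported, since the sources used here name no genome build.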

Results

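Mouse R1 ES cells in adherent and unattached culture were compared with neurospheres from the embryonic forebrain, each measured on MG_U74Av2 expression arrays. R1 is an established mouse ES cell line, and LIF is a cytokine that keeps such cells undifferentiated. Embryoid bodies are unattached clusters of ES cells, and these were kept with LIF for 48 hours. Neurospheres are floating clusters of neural stem and progenitor cells, and these came from the E13.5 embryonic telencephalon and grew with FGF2. Their labels name astrocytes, glia and oligodendrocytes as contaminating cells. There were 2 embryoid body arrays, titled aggregation and suspension, 1 adherent array and 1 neurosphere array, so the number of arrays limits the precision of every value. The neurosphere and adherent groups had no replicates.

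The deposited signals of the aggregation and neurosphere arrays were 45.5-fold and 50.3-fold below those of the suspension array, so all arrays were rescaled to one trimmed mean. The ratio of 3' to 5' signal for Gapdh control probe sets was 0.880 and 0.893 in the embryoid body arrays, 0.946 in neurospheres and 0.804 in adherent cells. For actin it was 1.20 and 1.11, 1.13 and 1.03 in the same order. After rescaling, the 10th percentile of signal was 17.4 in adherent cells and 29.5 to 33.8 in the other arrays, and the median was 178 against 225 to 242. Across the 6843 features, which are not independent replicates, log2 values of the embryoid body arrays correlated at r = 0.900. Each of them correlated with adherent cells at 0.882 and 0.875, and with neurospheres at 0.672 and 0.679.

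The first comparison asked how neural stem cell cultures differ from ES cells. Of the genes tested from fixed lists, 12 of 25 neural progenitor and radial glia genes rose in neurospheres and 0 fell, and 22 of 26 pluripotency genes fell and 0 rose. Fabp7, the brain lipid-binding protein of radial glia, had a scaled signal of 41867 in neurospheres, 47.7 ± 27.7 (SD, n = 2) in embryoid bodies and 15.5 in adherent cells. Bcan, a proteoglycan of brain extracellular matrix, had 10905, 82 ± 15 and 37.8 in the same order, and Ptprz1, a receptor phosphatase of glial precursors, had 4359, 37.2 ± 3.98 and 16.7. Pou5f1, the Oct4 transcription factor of pluripotent cells, had a signal of 51.3 in neurospheres against 9229 ± 1864 (SD, n = 2) in embryoid bodies and 10687 in adherent cells. Nr0b1, a nuclear receptor of ES cells, had 28.9, 6521 ± 1165 and 10535. Lower signals of Fabp7, Ptprz1 and Nr0b1 near or below the 10th percentile of an array were not told apart from background. No ratio of signals is therefore given for them here. Their log2 differences, given below, depend in size on the value added before taking log2.

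In limma's test, 561 features rose in neurospheres and 816 fell, among them 515 and 727 named genes, and 2234 had an unadjusted p under 0.05. Without any test, 628 features were at least 2-fold higher in neurospheres than in each R1 array and 641 were at least 2-fold lower. The same count with an R1 array in the place of neurospheres gave 65 higher and 110 lower for aggregation, 80 and 78 for suspension, and 98 and 240 for adherent cells. These counts are not like for like, since the R1 array then also had to differ from neurospheres. Against the other R1 arrays alone, aggregation was at least 2-fold higher in 178 features and lower in 175, and suspension in 245 and 146. The test counts moved to 219 and 245 without the intensity trend, which ended the calls of 23 of the 77 called genes named by rule, namely Cd68, Cdc20, Dll1, Eng, Fzd2, Gap43, Ier2, Jun, Krt8, Lama1, Mad2l1, Mcm2, Mcm3, Ncam1, Nes, Nkx2-2, Pdk1, Pim2, Pim3, Rbpj, Sfrp2, Sox10 and Stmn2. Without the signal filter 7 of the 77 calls ended (Dll1, Fzd2, Gap43, Lama1, Nkx2-2, Sfrp2 and Sox10), against the embryoid bodies alone 5 (Dpysl3, Krt8, Lama1, Sfrp2 and Sox10) and against the adherent array alone 4 (Cdh2, Dll1, Dpysl3 and Fzd2). Fits of 2 groups, neurospheres and R1, gave 381 and 566 with all arrays, 269 and 400 without the aggregation array, and 329 and 451 without the suspension array. The calls of Dpysl3, Sfrp2 and Sox10, lost without either embryoid body array, were also lost in the 2-group fit with all arrays (2.62, 1.40 and 0.99). In lists, the fit without the intensity trend called 0 astrocyte, neuron and Notch genes lower (2, 3 and 1 at an unadjusted p under 0.05), and 0 oligodendrocyte, endothelial and microglia genes either way (3, 2 and 3). It called 3 imprinted genes higher and 3 lower, 0 and 2 immediate early and stress genes, 1 and 1 Wnt genes, 1 and 2 endoderm genes, 1 and 0 primitive ectoderm genes, and 0 and 1 trophoblast genes. The median of all features lay at 0.10 on the log2 scale after trimmed-mean scaling and at 0.04 after quantile normalization.

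**Figure D1:**
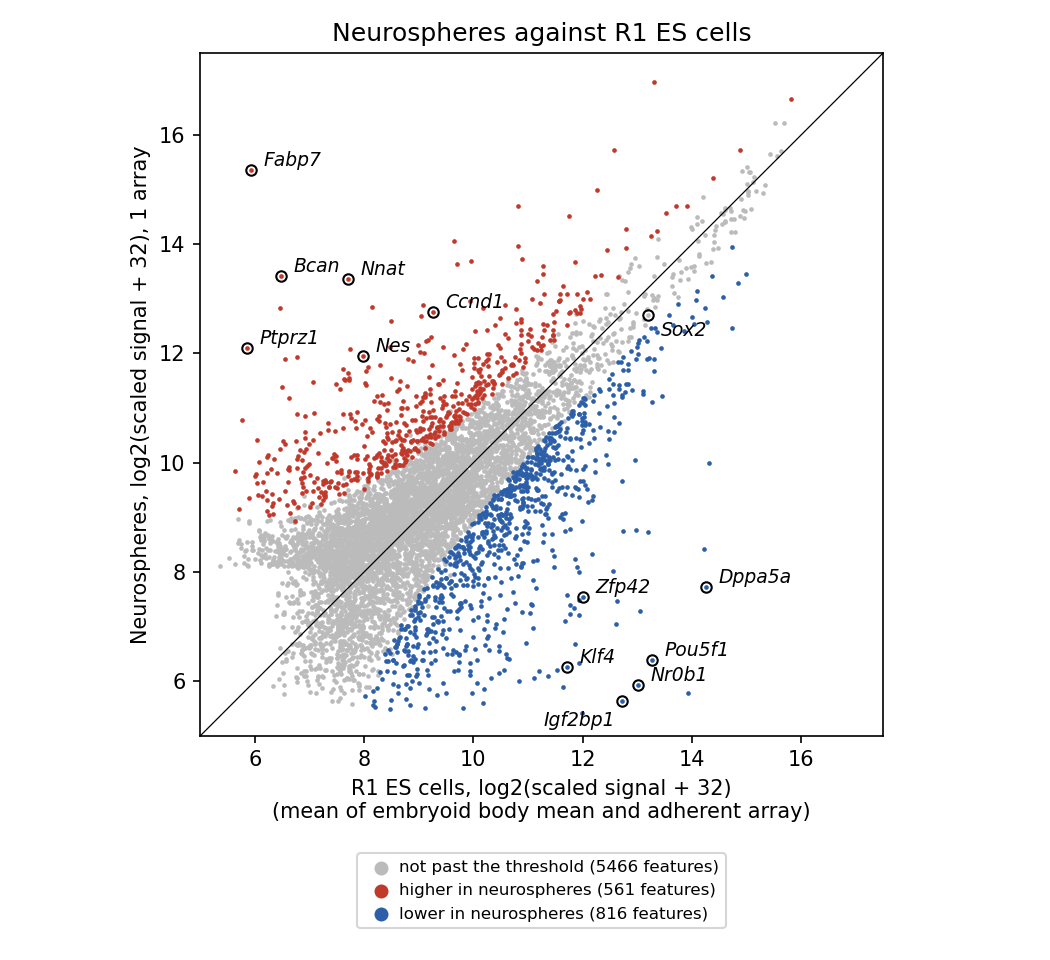
Each point is 1 of 6843 features, with log2(scaled signal + 32) in R1 cells (mean of the embryoid body mean and the adherent array) on the x axis and in the neurosphere array on the y axis. Red points (561) were higher and blue points (816) lower in neurospheres past the limma threshold, and circles mark genes named in the text, with Fabp7 and Bcan far above the diagonal and Pou5f1 and Nr0b1 far below it.

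The largest rises by the fixed rule were at least 2-fold against each of the 3 R1 arrays. Besides Fabp7 (9.43 ± 0.56 SE in log2, limma adjusted p = 6.87e-10), Bcan (6.94 ± 0.56, 4.44e-08) and Ptprz1 (6.24 ± 0.77, 9.57e-06) they were Pea15a, a phosphoprotein abundant in astrocytes (6.37), Nnat, an imprinted gene of the developing brain (5.66), and Adgrg1, an adhesion receptor of neural progenitors (5.35). Plat, the tissue plasminogen activator, rose by 5.16, Gria2, an AMPA glutamate receptor subunit, by 5.02, Marcks, a substrate of protein kinase C, by 4.72, and Pfn2, a profilin abundant in brain, by 4.56. The largest falls were those of Igf2bp1, an mRNA-binding protein (-7.09 ± 0.29, adjusted p = 3.11e-12), Nr0b1 (-7.09 ± 0.29, 3.11e-12) and Pou5f1 (-6.89 ± 0.28, 3.11e-12). Dppa5a, an RNA-binding protein of ES cells, followed at -6.53, Mtm1 at -5.81, Rps4l at -5.75, and Slc7a7, an amino acid transporter, at -5.73. Trap1a was at -5.61, and the Krüppel-like factors Klf5 and Klf4 were at -5.57 and -5.45. Dimmer probe sets lay at 3.27 for Bcan and 3.36 to 6.29 for Ptprz1, and did not share the direction for Mtm1 (0.20), Rps4l (0.86) and Pou5f1 (0.74). Because a side of these differences can lie near background, their size and order depend on the added 32. With 1 or 100 added, Fabp7 lay at 10.59 and 8.33, Igf2bp1 at -8.49 and -5.86, and Nr0b1 at -8.11 and -6.02. The Mtm1 and Rps4l probe sets used belong to classes, _f_at and _s_at, that can detect related transcripts.

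Of 26 pluripotency genes tested, 22 fell and 0 rose in limma's test, with 23 and 0 adjusted over the list alone and 23 lower and 0 higher at an unadjusted p under 0.05. The list's median of -3.88 lay at percentile 0 of the matched random lists. Zfp42, the Rex1 zinc finger gene, fell from 3344 ± 8.45 (SD, n = 2) in embryoid bodies and 5026 in adherent cells to 154 in neurospheres. Sox2, a transcription factor of both pluripotent and neural stem cells, did not pass the test (-0.50, adjusted p = 0.182), with a signal of 6644 in neurospheres, 9420.3 ± 793 in embryoid bodies and 9397 in adherent cells. Its probe set was of the _r_at class. Of 15 genes of the LIF and STAT3 response, 6 fell and 0 rose (6 and 0 adjusted over the list alone, median -0.89, percentile 0.44). They included the adhesion molecule Icam1 (-4.26), Klf4, the transcription factor Tfcp2l1 (-2.95; -0.14 on a dimmer probe set) and the kinase Pim3 (-2.41). Klf4 and Tfcp2l1 also belong to the pluripotency list and Icam1 to the adhesion list. The labels list LIF as a supplement of all 3 R1 cultures and FGF2 as that of the neurospheres.

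Of 25 neural progenitor and radial glia genes, 12 rose and 0 fell, with 15 and 0 adjusted over the list alone, a median of 2.10 and percentile 100. Nes, which encodes the intermediate filament nestin of neural stem cells, rose by 3.99 ± 0.66 (SE; adjusted p = 2.23e-04). Its signal was 3945 in neurospheres, 424 in aggregation, 52.5 in suspension and 289 in adherent cells. The filament genes Vim and Gfap did not pass the test, at 0.54 (adjusted p = 0.546) and 1.15 (adjusted p = 0.247). In the Notch pathway list of 14 genes, 3 rose and 1 fell, and 5 and 1 did so adjusted over the list alone (median 0.77, percentile 96.88). The target genes Hes5 (3.29) and Hey1 (2.96) and the ligand gene Dll1 (1.88) rose, and Rbpj, the DNA-binding partner of Notch, fell by 1.82. Dll1, Hes1, Hes5 and Notch1 also belong to the neural progenitor list, so the lists are not separate evidence. The Dll1 call ended without the suspension array, where its value was 1.45. In the Wnt pathway list of 16 genes, 3 rose and 1 fell, with the same numbers adjusted over the list alone (median 0.78, percentile 97.24). The receptor genes Fzd9 (3.36) and Fzd2 (2.67) rose and the repressor Tcf7l1 fell (-2.48). The call of Sfrp2, a secreted Wnt antagonist (1.56), ended without either embryoid body array, with values of 1.54 and 1.58.

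Of 28 neuron genes on the array, 16 reached the signal filter. Of these 16, 4 rose and 2 fell, with 9 and 3 adjusted over the list alone (median 1.42, percentile 99.99). The other neuron genes stayed below the array median on all 4 arrays, neurospheres included, so the median does not describe the whole list. Ncam1, a neural cell adhesion molecule, rose by 1.94 (0.79 on a dimmer probe set). The Ncam1 and Stmn2 calls ended with the mean of each gene's probe sets (1.37 and -1.27). Stmn2 fell by 1.92, although its dimmer probe sets ranged from -3.26 to 1.36. Gap43, a growth cone protein, and Dpysl3 rose by 2.11 and 2.72, but both calls ended without either embryoid body array, with values of 1.94 and 2.27 for Gap43 and 2.66 and 2.78 for Dpysl3. Tubb3, the neuronal tubulin, did not pass the test (0.70, adjusted p = 0.0666), and its dimmer probe set lay at -1.48. Of 11 astrocyte genes, 4 rose and 1 fell, and 4 and 1 adjusted over the list alone (median 1.28, percentile 99.8). The risers were Aldoc, an aldolase of astrocytes (4.34), Mt3, the brain metallothionein (3.94), Sparcl1, an extracellular matrix protein (3.89), and Cpe, carboxypeptidase E (3.87). Of 6 oligodendrocyte lineage genes tested, out of 10 on the array, 2 rose and 0 fell, also adjusted over the list alone (median 1.06, percentile 95.18). Nkx2-2 rose by 3.12, and the Sox10 call (1.16) ended without either embryoid body array, with values of 1.09 and 1.24. The Sox10 and Dpysl3 calls also ended after quantile normalization (1.16 and 2.55). The labels name astrocytes and oligodendrocytes among the cells contaminating the neurospheres. In 2 lists described next, few genes reached the signal filter: 6 of 15 on the array for microglia and macrophages and 4 of 10 for endothelium.

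In microglia and macrophages 0 of 6 rose and 1 fell (2 and 1 adjusted over the list alone, median 0.13, percentile 48.41, with medians of 0.44 without the aggregation array, -0.17 without the suspension array and -0.02 after quantile normalization), and Cd68, a lysosomal protein, fell (-1.78; call lost without the aggregation array, -1.72). In the endothelial list 0 of 4 rose and 1 fell (0 and 1 adjusted over the list alone, median -1.23, percentile 1.09), and Eng, the endoglin gene, fell (-1.47; call lost without the aggregation array, -1.45). In the fibroblast list 0 of 10 rose or fell, also adjusted over the list alone, with 1 higher and 1 lower at an unadjusted p under 0.05 (median 0.14, percentile 40.67, and 0.37 and 0.08 without the aggregation or suspension array and 0.24 without _r_at probe sets), and its members with the highest mean, Col1a2 and Col5a1, lay at 0.02 and -0.45. In primitive and visceral endoderm 1 of 15 rose and 4 fell, also adjusted over the list alone (median -0.42, percentile 3.14, with medians of -0.71 and 0.10 without the aggregation or suspension array and -0.68 after quantile normalization). Plat was the riser, and Rhox5 (-3.76), the laminin gene Lama1 (-2.85; call lost without the aggregation array, -2.42) and the protease gene Ctsl (-2.29) fell. The fixed endoderm gene Gata4 did not pass (1.10, adjusted p = 0.243). In the streak and mesoderm list 0 of 13 rose and 2 fell, also adjusted over the list alone (median 0.37, percentile 69, and 0.12 after quantile normalization): Nodal (-2.75) and Lefty1 (-2.60; -1.20 on a dimmer probe set), a signal of the Nodal pathway and its antagonist. In primitive ectoderm 1 of 5 rose and 1 fell, also adjusted over the list alone (median 1.04, percentile 95.41): Sox3, also a neural progenitor gene (2.10), and the kinase Pim2 (-1.71; call lost without the aggregation array, -1.65). In trophoblast 0 of 8 rose and 2 fell, also adjusted over the list alone (median -0.59, percentile 3.61): Tfap2c (-4.25) and the keratin Krt8 (-1.89; call lost without the suspension array, -1.82).

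**Figure D2:**
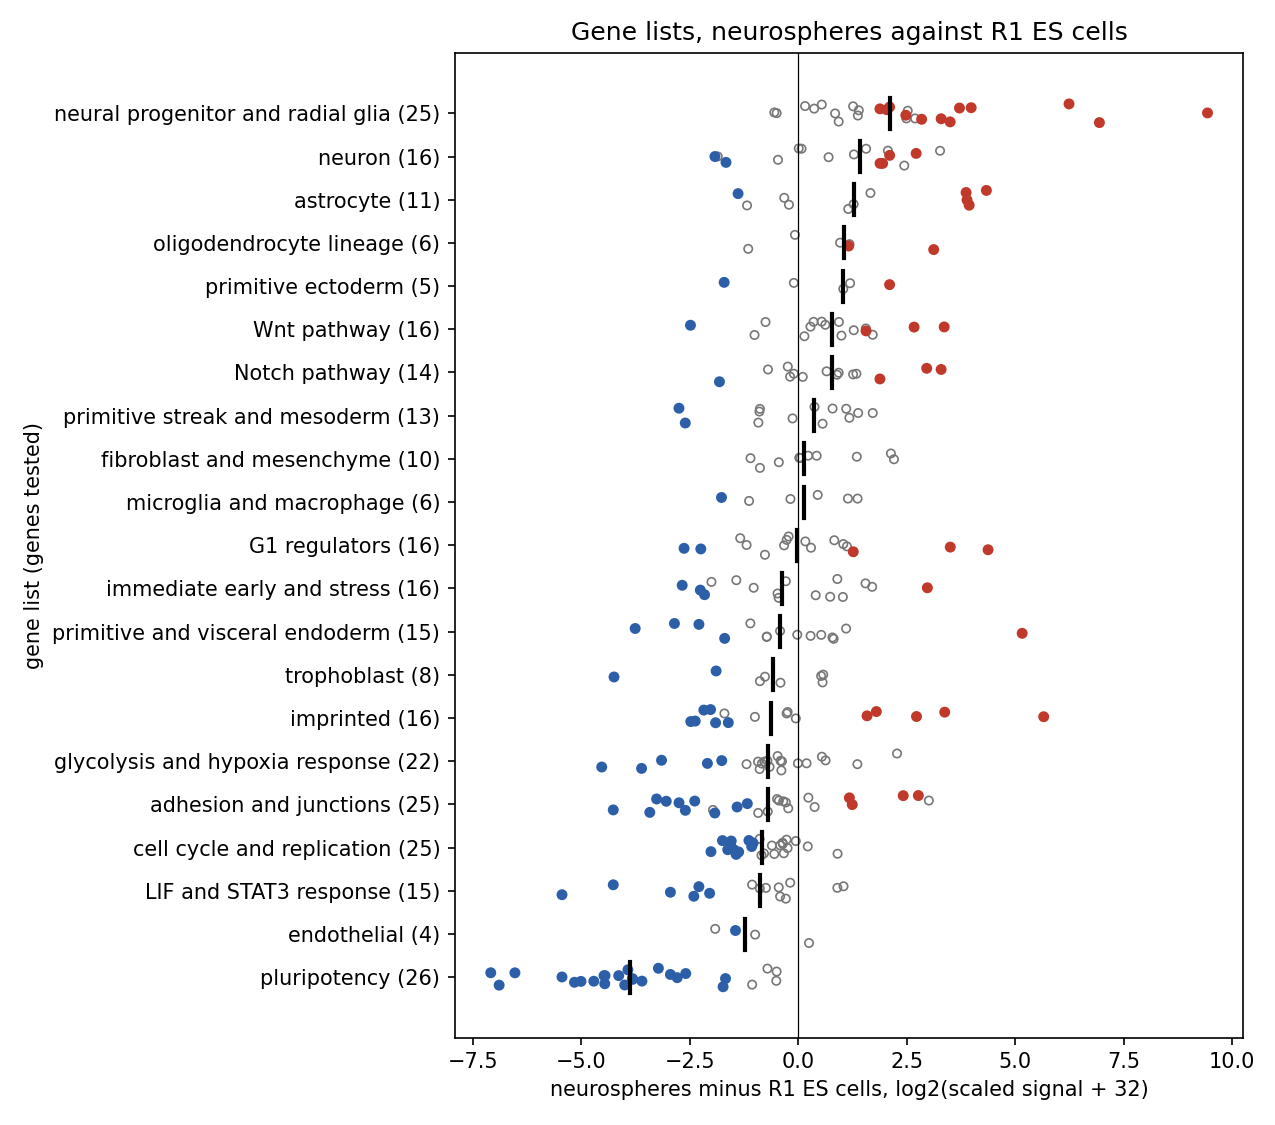
Log2 difference between neurospheres and R1 cells for each tested gene of the 21 fixed lists, with the number of genes tested beside each list name. Filled red and blue points passed the limma threshold, open points did not, and black bars are list medians, which run from -3.88 for pluripotency to 2.10 for neural progenitors.

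Of 25 cell cycle and replication genes, 0 rose and 11 fell, with 1 and 14 adjusted over the list alone and 1 and 15 at an unadjusted p under 0.05 (median -0.85, percentile 0.54). Without the intensity trend limma called 0 of the 25 either way, with 0 higher and 11 lower at an unadjusted p under 0.05. The replication helicase genes Mcm2 and Mcm3 fell (-2.01 and -1.75), and the spindle checkpoint gene Mad2l1 fell by 1.56. Cdc20, an activator of the anaphase-promoting complex, fell by 1.63, and this call ended without the aggregation array (-1.43). Of 16 regulators of G1 phase, 3 rose and 2 fell, with 4 and 2 adjusted over the list alone (median -0.03, percentile 29.71, with medians of 0.17 without _r_at probe sets and 0.04 without the aggregation array). Ccnd1 and Ccnd2, D-type cyclins of G1 progression, rose by 3.50 and 4.37, with signals of 6899 and 1339.9 in neurospheres. Ccnd1 had 828 ± 433 (SD, n = 2) in embryoid bodies, and Ccnd2 had 57.4 ± 24.7. A dimmer Ccnd1 probe set lay at 0.59, and Ccnd3, chosen after its values were seen, did not pass (0.16, adjusted p = 0.777). Cdk2, the kinase partner of cyclins E and A, and Gadd45a, a growth arrest gene, fell (-2.25 and -2.63).

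Of 22 glycolysis and hypoxia genes, 0 rose and 5 fell, with 0 and 8 adjusted over the list alone and 0 and 11 at an unadjusted p under 0.05 (median -0.69, percentile 0.87). Without the intensity trend 3 fell. Slc2a3 and Slc2a1, the transporters GLUT3 and GLUT1, fell, at -4.53 ± 0.28 (SE) and -3.15 ± 0.44. Hexokinase Hk2 (-3.61) and Pdk1, an inhibitor of pyruvate dehydrogenase (-2.09), fell as well, whereas the hexokinase gene Hk1 did not pass (-0.38, adjusted p = 0.311). Of 25 adhesion and junction genes, 4 rose and 10 fell, with 5 and 11 adjusted over the list alone (median -0.70, percentile 0.13). Without the intensity trend 2 rose and 6 fell. The falls included Icam1, the claudin Cldn4 (-3.42), the epithelial adhesion molecule Epcam (-3.27) and fibronectin Fn1 (-3.04). The integrin genes Itgb5 (2.42), Itgav (1.24) and Itgb1 (1.18), chosen after their values were seen, rose against the R1 mean, but against the adherent array alone they lay at 1.33, 0.73 and 0.22 and did not pass. Cdh2, the N-cadherin of neural tissue, rose by 2.77 (adjusted p = 0.0216), a call that ended with the filter at the 75th percentile (adjusted p = 0.0752) and against the adherent array alone (1.94), whereas Cdh1, the E-cadherin of epithelia, did not pass (-0.29, adjusted p = 0.626).

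Of 16 imprinted genes, 5 rose and 6 fell, with 5 and 8 adjusted over the list alone (median -0.63, percentile 0.69, and -0.25 and percentile 14.87 without _r_at probe sets). Nnat, Ndn (3.38), which encodes necdin of postmitotic neurons, and Gnas, a G protein subunit (2.73), rose, and Phlda2 fell (-2.48). Of 16 immediate early and stress genes, 1 rose and 3 fell, with 5 and 6 adjusted over the list alone (median -0.37, percentile 6.6). Jun rose (2.98), and the nuclear receptor Nr4a1 (-2.68), the chaperone Hsp90aa1 (-2.26) and Ier2 (-2.16) fell.

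**Figure D3:**
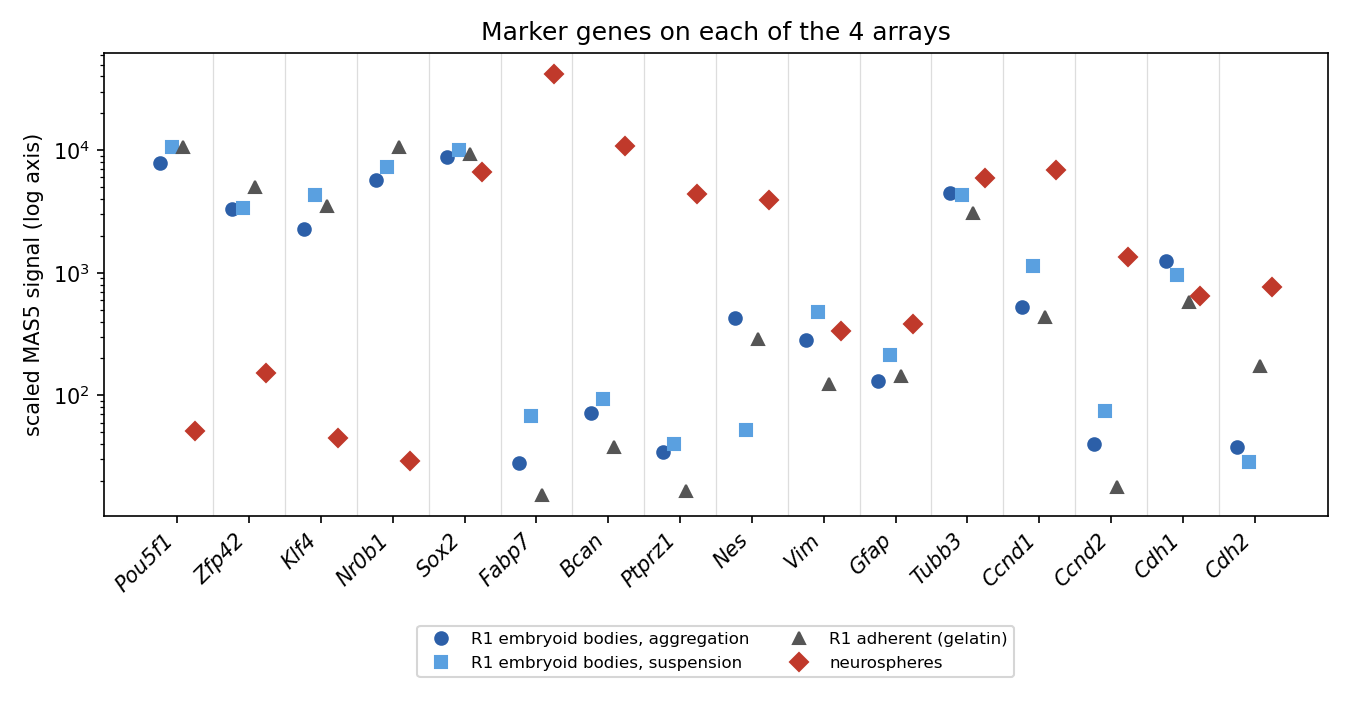
Scaled MAS5 signal (log axis) of 16 marker genes on each of the 4 arrays, 1 point per array. Pou5f1 is at 51.3 in neurospheres and between 7911 and 10687 on the 3 R1 arrays, whereas Fabp7 is at 41867 in neurospheres and between 15.5 and 67.3 on the others.

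The next comparison asked how unattached growth differs from adherent growth, and it shares the R1 arrays with the comparison above. Few genes passed the test, while the list of adhesion genes lay lower in embryoid bodies than on the single adherent array. Itgb1, the integrin subunit that pairs with most matrix-binding alpha chains, had a signal of 918 ± 453 (SD, n = 2) in embryoid bodies and 3340.1 in adherent cells, 3.77-fold lower (limma adjusted p = 0.0266). F2r, the thrombin receptor, was 4.41-fold lower and Pdia3, a protein disulfide isomerase of the endoplasmic reticulum, was 4.36-fold lower. Of the pluripotency genes, Pou5f1 was at -0.23 (0.98 on a dimmer probe set), Zfp42 at -0.58 and Sox2 at 0.00 in log2. Pou5f1, Zfp42 and Sox2 did not pass limma's test, and 0 of 26 pluripotency genes did, with 2 higher and 1 lower at an unadjusted p under 0.05. The Sox2 value came from an _r_at probe set. Against adherent cells, uncalled probe sets of that class lay 0.686 (aggregation) and 0.647 (suspension) above the others in the median, so 0.00 does not show an unchanged level.

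In limma's test 18 features were higher in embryoid bodies and 6 lower, and 983 had an unadjusted p under 0.05. After quantile normalization the counts were 12 and 2, so that the share of higher calls was 85.7% in place of 75%. All 18 higher calls of the main fit were also higher in neurospheres than in adherent cells. Their median difference from adherent cells was 1.18 in neurospheres and 1.65 in embryoid bodies. Over all features the median of neurospheres minus adherent cells was 0.21. Both differences use the same adherent array, so the choice of these features favoured a positive sign in neurospheres. For the 18 higher calls a low reading on the single adherent array cannot be told apart from a rise in embryoid bodies. The higher calls were led by Phf7 (2.60 ± 0.34 SE, adjusted p = 0.00152; dimmer probe sets 0.96 to 1.14), Mep1b, a meprin protease subunit (2.47; 0.24 on a dimmer probe set), and Mapk8ip1, a scaffold of JNK signalling (2.39). Uhmk1, a kinase (2.31; -0.39 on a dimmer probe set), and Psg17, a pregnancy-specific glycoprotein (1.98), followed. The lower calls were led by F2r (-2.14 ± 0.35, adjusted p = 0.00782; dimmer probe sets -0.12 to 0.42) and Pdia3 (-2.13 ± 0.31, 0.00365). Tmco1, a calcium channel of the endoplasmic reticulum (-1.99), Itgb1 (-1.91; -0.54 on a dimmer probe set) and Tmem131 (-1.84) came next. Of the 6 lower calls, Tmem131, Tmco1, Pdia3 and Selenot also read lower in neurospheres (538, 583, 2028 and 2640) than in adherent cells (2944, 2302, 4418 and 2895). Itgb1 and F2r read higher there (3898 and 4038, against 3340 and 2518). A high reading on the single adherent array cannot be told apart from a fall in embryoid bodies. Of the 18 higher calls, 14 were probe sets of the _r_at class, named after the ending of their identifiers. This is 77.78% (exact binomial 95% interval 52.36 to 93.59), against 4.5% of all features tested, and 0 of the 6 lower calls were of that class. Without this class, a setting chosen after seeing the data, 3 features were higher (Uhmk1, Psg17 and a probe set without a gene) and 2 lower (Pdia3 and F2r). Calls outside the class were lost there as well, with little change in value: Itgb1 (-1.87, adjusted p = 0.0768), Mapk8ip1 (2.41, 0.0683), Tmco1 (-1.95, 0.0791) and Tmem131 (-1.80, 0.0791). Limma called 0 features in either direction without the intensity trend or without the signal filter, and of the 24 calls 14 were shared after quantile normalization, where Itgb1 (-1.76), Psg17 (1.86), Mep1b (2.16), Mapk8ip1 (2.07), Tmco1 (-1.91) and Tmem131 (-1.73) did not pass. With the mean of each gene's probe sets 1 was higher and 1 lower, and Phf7, Mep1b, Uhmk1, F2r and Itgb1 lay at 1.57, 1.36, 0.96, -0.61 and -1.23 without a call.

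At least 2-fold differences in both embryoid body arrays were counted in 421 features that were higher and 197 that were lower than in adherent cells. After quantile normalization these counts were 248 and 257, and with suspension or aggregation as the only embryoid body array they were 920 and 521, and 802 and 545. With aggregation as the odd array the other R1 arrays were both at least 2-fold higher in 175 features and lower in 178, and with suspension in 146 and 245.

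Of 25 adhesion and junction genes, 0 were higher and 1, Itgb1, was lower in embryoid bodies over all features, and 1 and 4 adjusted over the list alone, with 3 higher and 7 lower at an unadjusted p under 0.05. The list's median was -0.76, at percentile 0 of the matched random lists, and 15 of the 25 genes were lower in both embryoid body arrays. The list was also low in neurospheres against the R1 mean (median -0.70), although Itgb5, Itgav and Itgb1 were not (1.33, 0.73 and 0.22 against adherent cells alone). For the list, a high reading on the single adherent array cannot be told apart from a fall in embryoid bodies. Besides Itgb1, the list-alone calls were the integrin subunits Itgb5 (-2.17) and Itgav (-1.02) and Icam1 (-1.65), and Tln1, the integrin-binding talin, was higher (0.83). Itgb5, Itgav and Tln1 were chosen after their values were seen. The listed Itga5 (-1.79), Itga6 (-1.24) and Itga3 (-0.42) did not pass, and integrin genes outside the list, also seen first, lay the other way without passing: Itgal 1.94, Itga4 1.66, Itgae 1.08, Itga7 0.61, Itgb7 0.40 and Itgax 0.29, with Itgb4 at -1.48. The median was -0.63 after quantile normalization, -0.78 without _r_at probe sets, and -0.48 and -0.58 with suspension or aggregation as the only embryoid body array.

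Of 10 fibroblast and mesenchyme genes, 1 was higher, Col1a2 (2.83-fold, adjusted p = 0.0294, _r_at class), and 0 lower, with 3 and 2 adjusted over the list alone (median 0.93, percentile 99.51). Without the aggregation array this median was 0.53 (percentile 84.91), and without the suspension array 1.27 (99.98). The other list-alone calls, chosen after their values were seen, were the matrix genes Dcn (2.19) and Col6a1 (1.16), and the smooth muscle genes Acta2 (-2.65) and Tagln (-1.44). In the other 19 lists 0 members passed limma's test, and 40 of their 261 distinct genes had an unadjusted p under 0.05, 25 higher and 15 lower. Adjusted over the list alone, 3 of 13 streak and mesoderm genes were higher and 0 lower (median 0.78, percentile 99.45, and 0.49 after quantile normalization). These were Msx1 (1.91), Mesp2 (1.47) and Hand1 (1.10), of which Msx1 and Mesp2 were chosen after their values were seen. Adjusted over the list alone, 2 of 16 immediate early and stress genes were higher and 0 lower (median 0.39, percentile 92.93), 1 of 16 Wnt genes was higher and 0 lower (median 0.25, percentile 69.71), and 1 was higher and 1 lower in each of the astrocyte (median 0.09, percentile 53.54), LIF and STAT3 (-0.15, 17.78) and G1 (0.28, 81.77) lists. Without the aggregation or suspension array the medians were 0.47 and 0.24 for Wnt, -0.29 and 0.45 for astrocytes, and 0.31 and -0.33 for LIF and STAT3. After quantile normalization those of astrocytes, LIF and STAT3, Wnt, and immediate early and stress genes were -0.20, 0.00, 0.11 and 0.21, and without _r_at probe sets the astrocyte median was 0.01.

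The remaining lists had 0 calls in either direction adjusted over the list alone. Pluripotency lay at a median of -0.17 (percentile 11.63), with Dppa5a at 0.65, and neural progenitors at 0.44 (90.36), with Hes1 at 0.44. Medians were 0.28 for neurons (72.83), 0.69 for the oligodendrocyte lineage (90.35), -0.13 for endothelium (22.55) and 0.46 for microglia (85.32). They were -0.07 for primitive and visceral endoderm (17), -0.07 for primitive ectoderm (30.71) and 0.32 for trophoblast (73.11). They were -0.10 for the cell cycle (31.96), 0.20 for glycolysis and hypoxia (81.78), -0.22 for imprinted genes (7.82) and 0.43 for the Notch pathway (91.84). Many of these medians moved or turned sign when 1 embryoid body array was left out. Without the aggregation or suspension array they were 0.63 and -0.14 for glycolysis and hypoxia (percentiles 99.82 and 12.83), 0.59 and 0.06 for neurons, and 0.39 and -0.31 for endoderm. In the same order they were -0.23 and 0.15 for primitive ectoderm, -0.07 and -0.31 for pluripotency, 0.51 and 0.15 for Notch, and -0.11 and 0.08 for endothelium. For trophoblast they were 0.18 and 0.19, for the cell cycle -0.18 and -0.14, and for imprinted genes -0.37 and -0.17. After quantile normalization the medians were 0.15 for neural progenitors, 0.13 for Notch, 0.15 for neurons, 0.37 for the oligodendrocyte lineage and 0.11 for trophoblast. They were -0.36 for endoderm, -0.36 for endothelium, -0.27 for primitive ectoderm, -0.11 for pluripotency, -0.06 for the cell cycle and 0.31 for microglia. Without _r_at probe sets they were -0.36 for endothelium, -0.06 for the cell cycle and -0.11 for imprinted genes. The list members Cdk4 (0.28), Pkm (0.77), Hsp90aa1 (0.51), Ctnnb1 (-0.55) and Tubb3 (0.52) did not pass the test. Among the fixed markers Nes was at -0.71, Vim at 1.37, Fabp7 at 0.70, Gfap at 0.19, Gata4 at 1.24, Cdh1 at 0.90 and Cdh2 at -1.66, none past the test. The median of all features was 0.10 after trimmed-mean scaling and 0.00 after quantile normalization.

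**Figure D4:**
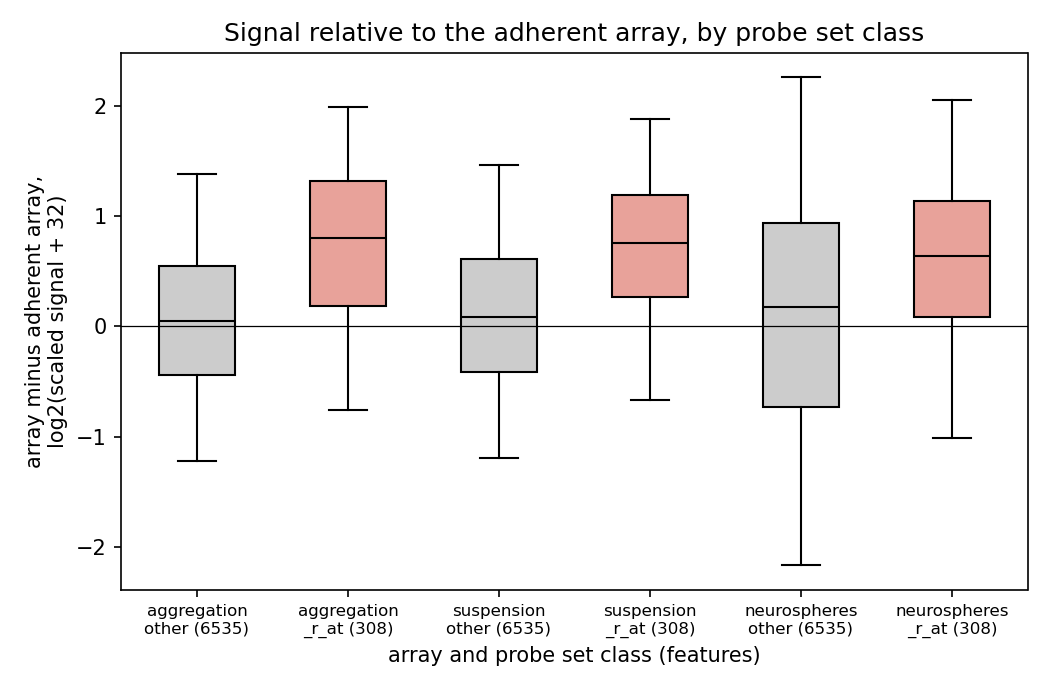
Log2 difference of the aggregation, suspension and neurosphere arrays from the adherent array for 308 features measured by _r_at probe sets and 6535 others; boxes span the quartiles, lines are medians and whiskers reach the 5th and 95th percentiles. The _r_at boxes lie above the others in all 3 comparisons.

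The aggregation and suspension arrays of embryoid bodies differed by at least 2-fold in 977 features, of which 428 were higher in aggregation and 549 higher in suspension. The SD of their log2 difference was 0.71, against 0.81 and 0.82 for the same arrays against adherent cells. Id2, an inhibitor of basic helix-loop-helix factors, had the largest difference, with 1869 in aggregation and 55.8 in suspension (21.6-fold), and its signal was 1379 in adherent cells. Cndp2 was 5.85-fold higher in aggregation, and Hoxb3 had 376 in aggregation and 39.7 in suspension. Zfp36, an immediate early gene of mRNA decay, was 9.63-fold higher in suspension, and Tiparp was 7.41-fold higher there. Cd160 had 331 in suspension and 19.5 in aggregation. The lower signals of Hoxb3 and Cd160, near or below the 10th percentile of their array, were not told apart from background, so no fold is given. With 1 array each, these differences were not tested.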

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

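The analysis without _r_at probe sets was chosen after seeing the data, and the other alternatives were planned. Without an embryoid body array no residual degree of freedom was left for embryoid bodies against adherent cells, so those alternatives are values with no test. For neurospheres the array left alone was assumed to vary like the others. No paired analysis was possible because no numbering links arrays of different groups. With values as deposited the 45.5-fold and 50.3-fold gaps in scale, a property of that alternative, entered every difference.

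With the alternatives on rescaled values, the log2 differences of named genes between neurospheres and R1 cells were unchanged in direction and side of the threshold in 1026 cases, lost the call in 63, gained one in 3 and moved in 6. For embryoid bodies against adherent cells the numbers were 494 unchanged, 45 lost and 15 moved. Of the 494, 56 came from the values without the aggregation array and 56 from those without the suspension array. These had no threshold and counted as unchanged when the shift stayed below the gene's residual SD. Leaving out 1 of 2 arrays always stays below it, so these cases do not show stability of direction or size. Counts of list members were within 1.5 times in 826 cases and outside in 56, and list medians moved in 63 of 168 cases. Of the 1377 calls for neurospheres, 1253 were shared after quantile normalization, 1348 and 1338 with pseudocounts of 1 and 100, 1347 without _r_at probe sets, 945 with 2 groups, 943 without the filter and 412 without the intensity trend. Neurosphere counts stayed within 1.5 times under quantile normalization, both pseudocounts, the mean of a gene's probe sets and the analysis without _r_at probe sets.

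Quantile normalization left 2 lower calls for embryoid bodies against adherent cells and 248 features at least 2-fold higher. With a pseudocount of 100, 216 and 121 features were at least 2-fold higher and lower in embryoid bodies, and 606 were at least 2-fold apart between aggregation and suspension. Without the filter, 0 features were called higher and 0 lower in embryoid bodies, and 1469 differed between aggregation and suspension. With the filter at the 75th percentile, 11 were called lower in embryoid bodies, 402 were at least 2-fold higher in neurospheres, 133 and 116 were at least 2-fold higher and lower in embryoid bodies, and 301 differed between aggregation and suspension. Without the intensity trend, 219 and 245 were called higher and lower in neurospheres, and 0 and 0 in embryoid bodies. With the mean of a gene's probe sets 1 was called higher and 1 lower in embryoid bodies. Against the adherent array alone, 1601 and 1259 features were at least 2-fold higher and lower in neurospheres, since fewer arrays had to be passed. Without _r_at probe sets 3 were called higher and 2 lower in embryoid bodies. Leaving out an embryoid body array gave 269 to 329 higher and 400 to 451 lower calls in neurospheres, and 802 to 920 features at least 2-fold higher and 521 to 545 lower in embryoid bodies, where only 1 array had to pass. For the other settings the cause was not tested.

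With values as deposited, 0 features were called higher and 0 lower in either comparison. At least 2-fold differences numbered 2 higher and 406 lower in neurospheres, 0 higher and 588 lower in embryoid bodies, and 6838 between aggregation and suspension. Of the calls in neurospheres, 22 turned negative: Aldoc -0.0295, Ccnd1 -0.85, Cdh2 -1.29, Cpe -0.40, Dll1 -2.09, Dpysl3 -0.88, Fzd2 -1.68, Fzd9 -0.94, Gap43 -1.81, Gnas -1.56, Hes5 -0.73, Hey1 -1.01, Jun -0.84, Mt3 -0.37, Ncam1 -2.11, Ndn -1.04, Nes -0.22, Nkx2-2 -1.20, Sfrp2 -2.28, Sox10 -2.75, Sox3 -2.01 and Sparcl1 -0.0261. In embryoid bodies Col1a2 (-1.14), Psg17 (-0.53) and Uhmk1 (-0.37) turned negative. Signals near background limit all fold changes of dim genes, since no detection calls were used.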

Other observations

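The test of a remaining scale effect was chosen after the result was seen, as were the gene groups described first, and the test within genes was chosen after that of the whole probe set class. Genes of cholesterol and fatty acid synthesis were among the larger rises in neurospheres. Scd2, a fatty acid desaturase, rose by 3.87 in log2, with a signal of 26437 in neurospheres, 1058 and 2651 in aggregation and suspension and 1875 in adherent cells. Dhcr7 (3.41), Scd1 (3.08), Idi1 (3.07), Hmgcs1 (3.07) and Fdps (2.83), enzymes of the same pathways, also rose in limma's test. Genes for Ndufb subunits of mitochondrial complex I formed another group: 6 of 9 rose and 0 fell (median 0.98), with Ndufb7 at 1.39, Ndufb10 at 1.37 and Ndufb5 at 1.11. Among 89 families of at least 8 genes with a shared name this gave a p of 2.60e-05 in a Fisher exact test of higher calls, and 0.00463 after Benjamini-Hochberg adjustment over the tests of higher and of lower calls together. Genes of a family are not independent replicates and there was 1 neurosphere array, so this p does not measure spread between cultures. Of the Ndufa genes 4 of 10 rose and 1 fell (Fisher adjusted p = 0.322 for higher calls). All 9 Ndufb genes lay above 0, also after quantile normalization, whereas 0 of 9 were called without the intensity trend.

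Genes of the sex chromosomes gave these levels. Xist, the RNA that coats the inactive X chromosome, had a signal of 302 in neurospheres, 39.4 and 32.7 in embryoid bodies and 14.5 in adherent cells, and its difference did not pass the test (adjusted p = 0.138). The Y-linked gene Eif2s3y had 115 in neurospheres, 633 and 453 in embryoid bodies and 790 in adherent cells (adjusted p = 0.00256, _f_at class). Uty, also Y-linked, had 22.9, 172 and 158, and 112 in the same order. Some other Y-linked probe sets did not share this pattern: 1 for Uba1y had 173 in neurospheres, 85.6 and 147 in embryoid bodies and 55.1 in adherent cells, and that of Kdm5d had 60.5, 141 and 50.5, and 73.3.

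The rise of the 6 synthesis genes may be part of a wider rise of sterol and fatty acid synthesis in neurospheres. Before their values were seen, 27 further genes of these pathways were listed, and 16 were tested. Of these 10 rose and 0 fell in limma's test, 14 lay above 0, and their median of 1.26 lay at percentile 100 of 10000 matched random lists. Cyp51 (2.33), Nsdhl (2.08) and Fads1 (2.05) rose, whereas Fasn (0.48), Acly (-0.03) and Ebp (-0.08) did not pass, and without the intensity trend 0 of the 16 were called. Growth medium, cell type and the use of a single neurosphere array stay open as explanations, untested.

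Most features called higher in embryoid bodies than in adherent cells were _r_at probe sets, and a lower reading of this class on the adherent array is a candidate explanation. With called features left out, the median difference between neurospheres and adherent cells was 0.448 higher for 441 _r_at probe sets than for 7566 others (95% bootstrap interval 0.369 to 0.516). The class also differed, by less, among the other arrays, so its shift was not confined to the adherent array. Its values were -0.210 and -0.109 for neurospheres against aggregation and suspension, and 0.139 for aggregation against suspension. Within 223 genes measured by an _r_at and another probe set, none of them called, the _r_at difference between embryoid bodies and adherent cells lay 0.5025 higher in the median (95% bootstrap interval 0.402 to 0.675) and higher in 159 genes. For these uncalled genes this argues against a response to unattached growth with no part of the class, which would have moved both kinds of probe set alike. The called _r_at features were left out, and their differences of 1.31 to 2.60 were larger than this shift. How much of those differences the class accounts for was not tested. Calls outside the class are not covered, neurospheres also grew unattached, and why the class differs was not tested.

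The aggregation and neurosphere arrays were deposited at a far lower scale, and an effect of scale that stays after rescaling could move both together. Across features, which are not independent replicates, the difference of aggregation from suspension and that of neurospheres from adherent cells correlated at r = -0.0571 (95% bootstrap interval -0.0827 to -0.0327). A large shared effect would have given a positive value, so the tables argue against a large general effect. The difference of neurospheres from adherent cells also holds the contrast between the cells (SD 1.378, against 0.708 for aggregation from suspension). A small shared effect could therefore be missed, and the size that could be detected was not tested. Effects on single genes stay open.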
